A study of Mus musculus with 2 samples.

How the data were processed

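The series comprises 2 ChIP-seq libraries of mouse E14 embryonic stem cells, one from cells labelled Bio-Tdg and one from cells labelled BirA (mock). Groups were taken from the ChIP label of each sample. Per the labels' protocols, chromatin of fixed cells was extracted in an SDS buffer, sonicated and immunoprecipitated, and libraries were made with a NEBNext ChIP-Seq kit. The same label also names a bisulfite kit, without saying to which libraries of the study that step applies. The submitters' processing notes name CASAVA 1.8, Bowtie 0.12.7, MACS 1.4.1 and the build mm9, with no role or order. The peak threshold, the control library and the read filters are not given in the sources used here. Whether the mock served as the control in peak calling is not stated either.

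The file analysed was the deposited peak list of the Bio-Tdg library, with 1 row per peak. No file of the mock library was analysed. Peak names run from 1 to 72970 in the form that MACS writes. The score in the fifth column is the authors' deposited value per peak. In the output of MACS 1.4 this column is −10 times the log10 of the peak's p-value. It was used to describe, rank and filter peaks within the list, and to recover reads per peak as set out below. The deposited start and end columns give the other values used, and positions are printed counting from 1. They were taken as mm9, the build in the submitters' processing notes. On 10 chromosomes the last peak lies beyond the last gene of the later build GRCm38. A peak can lie beyond the last gene in any build, so this count does not by itself tell the builds apart.

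Reads per peak were recovered from score and width, a step chosen after seeing the data. A single background rate was fitted, so that each score equals −10 times the log10 of the Poisson probability of more than a whole number of reads when the mean is the rate times the peak width, with a width of at least 370 bp. The list has 9 peaks narrower than that. Of 70884 peaks with a score below 3050, 70884 lay within 0.01 score units of such a value, where chance would place 0.119%, since 1 read changes the score by a median of 16.6. The numbers are 1 higher throughout if the caller used the probability of at least that number. At higher scores the p-value reaches the limit of double-precision numbers, and no reads were recovered for 2086 peaks. On simulated data, 100% of reads were recovered for 20000 peaks under a single rate, and under a background that varied from peak to peak 0.195% of scores lay within the tolerance. The recovered reads sum to 4201581. This is a sum over part of the peaks and not the depth of the library, and reads without molecular identifiers are not independent molecules.

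Peaks per chromosome were compared with the number expected from the length between the first and last peak of chromosomes 1 to 19 and X, with exact 95% Poisson intervals. Chromosome Y and the mitochondrial genome were left out. Spacing was tested by a two-sided permutation test on the median distance between midpoints of neighbouring peaks, with 1000 random placements between the first and last peak of each chromosome that had at least 100 peaks, 72942 peaks in all. On simulated peaks the ratio to random was 1.00 (permutation p = 0.786) for uniform placement and 0.868 (permutation p = 0.00995) for a clustered one. Bins of 1 Mb were compared with 200 random placements, distances under 5 kb with 100, and the bootstrap used 200 draws. Score and width were compared by Spearman's rho and Pearson's r without a p, as peaks of a single library are not replicates. With 1 library per group, no test between samples was made.

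The designs and the first set of alternatives were fixed before the data were examined. They were a score of at least 100, merging of peaks less than 1 kb apart, bases covered in place of peak counts, and leaving out the widest 1% of peaks. Scores of at least 500 and 1000, merging within 5 kb, placement within 1 Mb bins (alone and with merging within 5 kb), leaving out chromosome 11 and reads in place of score were added after seeing the data. Named peaks followed a rule fixed beforehand for the case that no mm9 annotation is used, which takes the 5 highest-scoring peaks, with ties ordered by width, and the 5 widest. Comparisons that need mm9 sequence or gene positions were not run. These were overlap with transcription start sites and CpG islands, genomic classes, base composition, start-site against distal peaks, promoter CpG classes, gene lists and motifs. The RefSeq gene table at hand is on GRCm38.p6. It was used only for the comparison of last peaks with last genes above and for the number of protein-coding genes per chromosome in the additional observations. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.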

Results

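Binding of Tdg was measured by Biotag ChIP-seq in E14 cells, a line of mouse embryonic stem cells. Tdg is thymine DNA glycosylase, the enzyme that excises 5-formylcytosine and 5-carboxylcytosine, the oxidised forms of methylcytosine, as part of active DNA demethylation. In Biotag ChIP a protein carries a short peptide that the bacterial ligase BirA biotinylates in the cell, so that the protein and the DNA bound to it can be pulled down on streptavidin. The series held 2 ChIP libraries. One came from cells with biotin-tagged Tdg (Bio-Tdg, n = 1) and the other from cells labelled BirA mock (n = 1). The Bio-Tdg library came with a list of called peaks, and no file of the mock library was analysed here. The Bio-Tdg list was therefore described on its own, no background measured in the mock can be set beside it, and no value has a replicate error. Intervals and permutation tests refer to peaks within this list. They cover counting or placement error only and say nothing about variation between cultures. The Poisson intervals also take peaks as independent of each other, and are too narrow where peaks cluster, as they did here. All positions are in the mouse build mm9.

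The Bio-Tdg list held 72970 peaks that covered 78.7 Mb. The median peak was 850 bp wide, with quartiles of 613 and 1307 bp, and 1400 peaks were wider than 3 kb. Scores, which are the authors' own value per peak, ran from 258 to 3233 with a median of 553. For 70884 peaks the score corresponded to a whole number of reads over a single fitted rate of 1.13 reads per kb, within 0.01 score units, and the number of reads could be read back. Those peaks held 21 to 239 reads, with a median of 41 and quartiles of 26 and 77. Their median density was 49.5 reads per kb, 43.8 times that rate, whose origin is not known, so the ratio is not an enrichment over a measured background. The 10% of these peaks with the most reads held 27.4% of the recovered reads. The other 2086 peaks had scores too high for the number of reads to be recovered, so 239 need not be the maximum of the list, and the total depth of the library is not known.

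**Figure D1:**
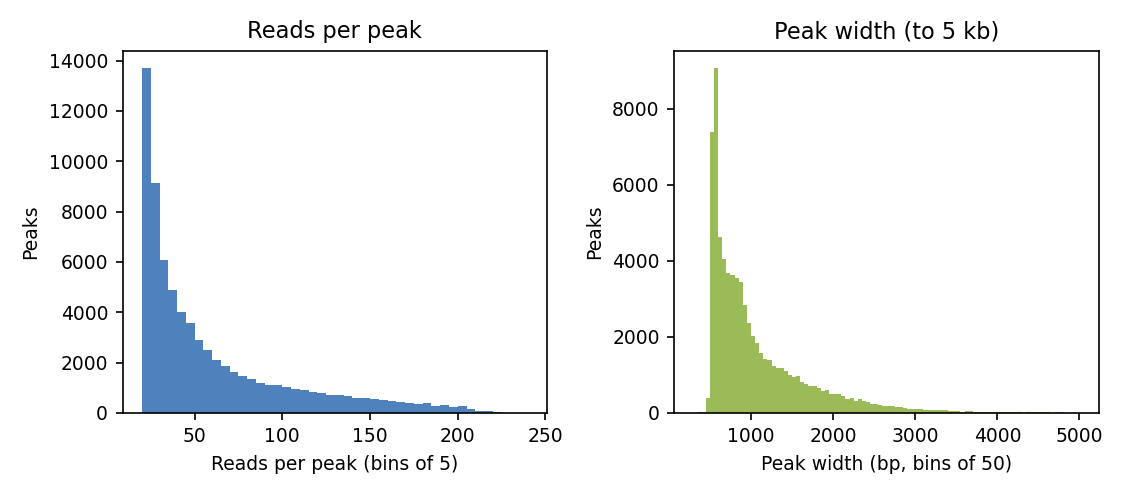
Distribution of the Bio-Tdg peaks by recovered reads per peak in bins of 5 reads (left, 70884 peaks) and by width in bins of 50 bp up to 5 kb (right). Both distributions are highest near their lower end, and the medians are 41 reads and 850 bp.

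The first comparison asked how Tdg peaks were spread over the chromosomes relative to chromosome length. Chromosome 11 carried the most peaks for its length. Its 6626 peaks gave 55.8 peaks per Mb (exact 95% Poisson interval 54.5 to 57.2), against 29.995 per Mb over the 19 autosomes together. Chromosomes 19 and 17 followed with 41.6 and 38.5 peaks per Mb. Chromosomes 14 and 3 had the fewest among the autosomes, at 19.4 and 19.8 peaks per Mb. Chromosome X, which E14 cells, being male, carry once, had 715 peaks or 4.45 per Mb (4.13 to 4.79), a density 6.74-fold lower than on the autosomes (6.27 to 7.27).

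Relative to the number expected if the peaks of chromosomes 1 to 19 and X were spread evenly over their length, chromosome 11 had 1.97 times as many (1.92 to 2.01) and X had 0.157 times as many (0.145 to 0.169). Of the 19 autosomes, 11 lay above and 8 below the expected number, each by more than its interval. These intervals are too narrow for peaks that cluster, as described below, so calls close to the expected number are uncertain. Chromosome 10 lay closest to the expected number, with a ratio of 1.05 (1.02 to 1.08). That number is lowered by the sparse X. Against the 29.995 peaks per Mb of the autosomes together, chromosome 10 had 29.8 (28.9 to 30.8). Chromosome 8 had 30.6 (29.6 to 31.5), so both intervals hold the autosomal value. Among peaks with a score of at least 1000, chromosome 10 no longer differed from the expectation (1.02, 0.959 to 1.08) and the ratio of X fell to 0.0389 (0.0289 to 0.0513). Peaks on X were also weaker than autosomal peaks. Their median was 33 reads against 42, their median width 720 against 852 bp and their median density 46.3 against 49.5 reads per kb. Length was taken from the first to the last peak of each chromosome.

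**Figure D2:**
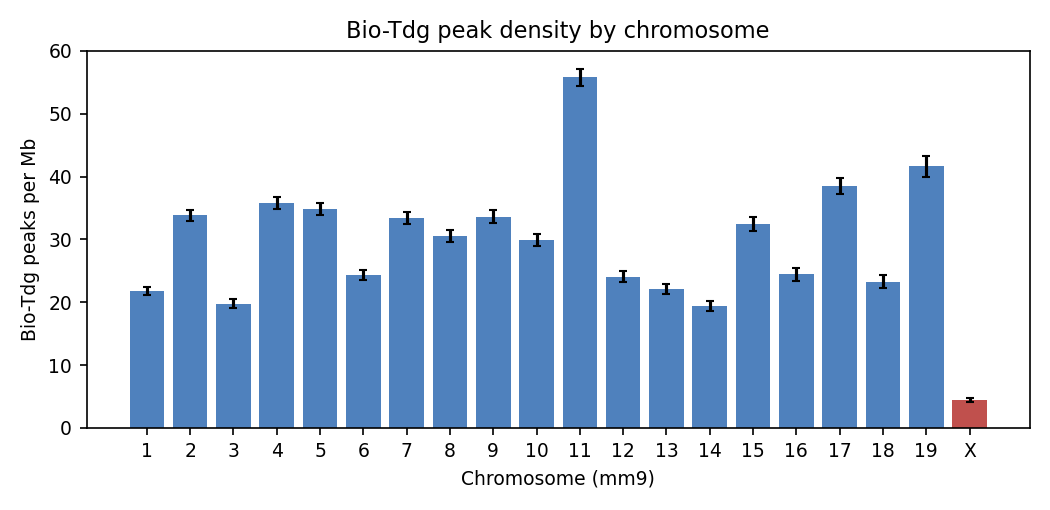
Bio-Tdg peaks per Mb on each autosome (blue) and on X (red). Bars give the number of peaks divided by the length from first to last peak, and error bars are exact 95% Poisson intervals of the count. Chromosome 11 reaches 55.8 and X lies at 4.45 peaks per Mb.

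Within chromosomes the density of peaks was uneven. The megabase with the most peaks was chromosome 10, 79000001 to 80000000, with 238 peaks, and the next megabase, 80000001 to 81000000, had 227. Chromosome 11 followed with 223 peaks between 97000001 and 98000000, and a stretch of 3 adjacent megabases from 115000001 to 118000000 on the same chromosome held 201, 203 and 201 peaks. Chromosome 7, 52000001 to 53000000, had 206 peaks. On X the most crowded megabase, 7000001 to 8000000, had 54. Over all 2583 bins of 1 Mb the median was 14 peaks, and the fullest 10% of the bins held 40.02% of the peaks, against a mean of 17.8% and at most 17.9% in 200 random placements. At the other end, 237 bins had no peak, against a mean of 2.77 and at most 7 in the random placements, in which assembly gaps were not left out. The longest autosomal stretch without a peak was chromosome 7, 39057428 to 46529253, at 7.47 Mb. On X a stretch of 10.2 Mb from 23270591 to 33427910 had none. The part of the chromosome farther from the low-coordinate end, where mouse centromeres lie, held more peaks on 14 of the 19 autosomes and fewer on 4, and chromosome 19 was tied. The call depended on that tie. An exact two-sided binomial test, chosen after seeing the data, gave p = 0.0636 with the tie counted against the difference and p = 0.0309 without chromosome 19. The ratio of the far to the near part ran from 0.394 on chromosome 16 to 4.02 on chromosome 15.

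**Figure D3:**
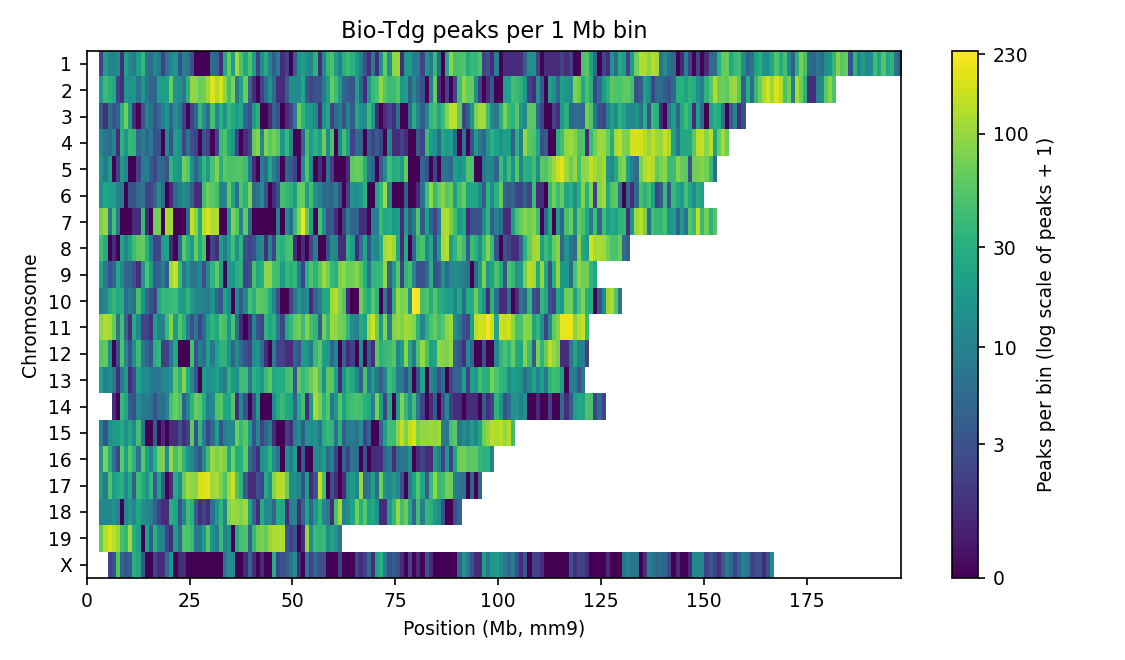
Number of Bio-Tdg peaks in each 1 Mb bin along chromosomes 1 to 19 and X (position in Mb, mm9). The colour scale is logarithmic in the number of peaks plus 1, and white marks positions outside the first and last peak. The brightest bins are on chromosome 10 near 80 Mb, with 238 and 227 peaks, and on chromosome 11, and 51 of the 162 bins of X hold no peak.

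The second comparison asked whether Tdg peaks lay closer together than random placement gives. The median distance between the midpoints of neighbouring peaks was 7278 bp, against a mean of 22268 bp when the same number of peaks was placed at random on each chromosome, a ratio of 0.327 (two-sided permutation test, p = 0.002, the smallest that 1000 draws can give). Of the distances, 40.2% were under 5 kb, against 14.7% at random, and 16.7% were under 2 kb. Assembly gaps were not left out of the random places, which can lengthen the random distances and lower the ratio. When random places were kept within the same 1 Mb bin, so that the crowding of whole megabases was preserved, the ratio rose to 0.630 (permutation p = 0.002), and when peaks less than 5 kb apart were also merged it was 0.840 (permutation p = 0.002). Both of these settings were chosen after seeing the data. Merged peaks cannot lie less than 5 kb apart but the random places could, which raises the ratio of 0.840. A neighbour within 5 kb was present for 43628 peaks, whose median score was 564, and 3551 peaks had none within 50 kb and a median score of 469. A random isolated peak had the higher score in a share of 0.458 of pairs with a random peak of the first kind (bootstrap 95% interval over peaks 0.448 to 0.467). Scores of adjacent peaks were barely related, with a rank correlation of 0.0082 (permutation p = 0.178).

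**Figure D4:**
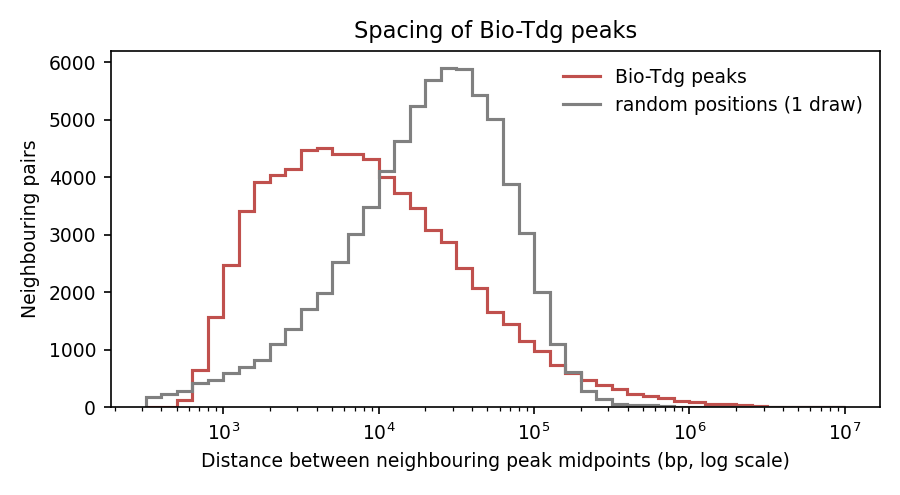
Distances between midpoints of neighbouring Bio-Tdg peaks (red) and of the same number of randomly placed peaks (grey, 1 draw), on a logarithmic axis in bp. The Bio-Tdg distances have a median of 7278 bp and the random placements a mean median of 22268 bp.

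The third description concerned score and width. Across peaks, which are not independent replicates, Spearman's rho between them was 0.972 and Pearson's r of the log10 values 0.969, and rho within single chromosomes ran from 0.941 to 0.976. For the peaks with recovered reads the score is a function of reads and width, so it is not a measure independent of width. In that function a wider peak with the same number of reads has a lower score. The positive relation therefore goes with the reads, which rose with width (Spearman's rho 0.980). Read density rose with width as well, from a median of 41.7 reads per kb in the narrowest of 4 equal groups of the peaks with recovered reads to 69.0 in the widest.

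Individual peaks were named by score and by width. The highest score, 3233, is the largest that a double-precision p-value can give, and 6 peaks shared it, so it does not rank them. Another 1649 peaks, among them the widest of the list, shared the commonest score of 3100, and 312 peaks lay above it. The highest-scoring peaks are therefore not necessarily the strongest. The widest of the 6 was chromosome 16, 31506514 to 31509775, at 3262 bp. It was followed by chromosome 4, 101027002 to 101030210, chromosome 1, 134053736 to 134056773, chromosome 15, 25550912 to 25553622, and chromosome 13, 73899908 to 73902567, which were 3209, 3038, 2711 and 2660 bp wide. The sixth, chromosome 17, 15840949 to 15843599, was 2651 bp wide and falls outside the rule of 5 peaks. The widest peaks of the list were both near the start of chromosome 11, at 3059334 to 3100222 with 40889 bp and at 3030350 to 3049031 with 18682 bp. The next was chromosome 4, 132593970 to 132604635, with 10666 bp. Chromosome X, 166426400 to 166436431, near the last peak of that chromosome, had 10032 bp, and chromosome 2, 165704106 to 165713580, had 9475 bp. All 5 of the widest peaks had the score of 3100. No gene annotation of mm9 was used here, so the genes at these positions are not given.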

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

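All tests in this part were chosen after the results were seen. Chromosome Y carried 27 peaks, which were outside the chromosome and spacing comparisons. They stand out because 25 of them lie in 125 kb, between 2777419 and 2902463, where peaks cover 42.2% of the sequence. The other 2 lie between 1790129 and 1793011. No mock value can be set beside them.

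After merging peaks less than 1 kb apart, the longest run of the list was chromosome 11, 3025458 to 3100222, with 7 peaks over 74.8 kb and 98.0% of it covered, followed by Y, 2875810 to 2902463, at 26.7 kb, and X, 166414624 to 166439474, at 24.9 kb. On Y 25.9% of the peaks (7 of 27) had scores too high for reads to be recovered, against 2.87% on the autosomes, but this does not exclude binding of single-copy sequence at the autosomal level, since the Y peaks stood out by their width (median 1481 against 852 bp), which the score follows closely, and 25 of them form a single cluster. A candidate explanation is repeated sequence that the cells hold in more copies than the build. If such sequence lay mainly near chromosome ends, which the explanation does not require, further long runs would be found there. Of the other 17 among the 20 longest runs, 0 lay within 1 Mb of a first or last peak. With 1.73% of all peaks in such places, 17 runs are too few to decide. The runs on Y, X and the start of 11, which lie near such a peak, gave the idea and were set aside after a first count had included them. On Y this nearness was fixed in advance, since all its peaks lie between 1790129 and 2902463. Repeats and binding cannot be told apart for these runs without repeat annotation or the mock, and no biological explanation was tested.

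Chromosome X had a peak density 6.74-fold lower than the autosomes. A lower number of genes was argued against as the whole cause: X had 0.740 peaks per protein-coding gene (0.687 to 0.796), and the autosomes had 2.46 to 4.18. A single copy of X could halve the reads of each peak and leave its width. X peaks of at least 25 reads would then be as dense as autosomal peaks of at least 50 reads only if all were still called. The ratio was 0.248 (0.227 to 0.270). It fell to 0.234, 0.225 and 0.190 for X limits of 30, 40 and 50 reads against autosomal limits of 60, 80 and 100. These ratios cannot decide, because reads per kb would be halved too. Recovered densities in the list started at 32.1 reads per kb and had an autosomal median of 49.5. Many halved peaks could therefore go uncalled. If a single copy halved the read density against a fixed calling limit, the ratio at the first percentile of density was 1.401 (1.30 to 1.51). It was 1.81 and 1.84 at higher limits, but this test was added once the other had come out low. It also decides little because peak edges may hold the density near the limit, with an autosomal upper quartile of 61.3 reads per kb against the 76.1 required. Loss of weak peaks from a single copy stays open as a part or the whole of the deficit. So does a difference in binding, for which no test was made.

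The scores of the 70884 peaks with recovered reads depended on reads and width alone, and the other 2086 were not tested. A local background, or one taken position by position from the mock, is argued against for the former, since the largest deviation from the score of a whole number of reads under a single rate was 0.00503. The rate is also unlikely to be the mean of this library over the chromosomes, as the recovered reads were 1.45 times the number that the rate gives for the whole length of 2569 Mb. Where the rate came from stays open, and so does whether peaks were filtered against the mock. No biological explanation was tested here.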

How the results depend on the processing

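The settings with a score of at least 500 or 1000, merging within 5 kb, placement within 1 Mb bins and no chromosome 11 were added after seeing the data. The number of peaks was 39635 at a score of at least 500 and 20562 at a score of at least 1000, and both follow from the threshold itself. Merging within 1 kb left 59221 runs. A score of at least 100, the stricter threshold set beforehand, removed no peak, so it says nothing about stability. Chromosome 11 stayed above its expected number, with ratios of 2.13 at a score of at least 1000 and 2.08 in bases covered, and X stayed below it, with 0.0389 and 0.119. Peaks on X had lower scores (median 416 against 555 on the autosomes) and smaller widths (median 720 against 852 bp). Both settings therefore lower the ratio of X and are no independent check on its deficit. Chromosome 10 lost its excess at a score of at least 1000 (1.02), for which the cause was not tested. That excess had come from X in the expected number, since the density of chromosome 10 lay below that of the autosomes together. The other 17 autosomes, without 10 and 11, kept their side in both settings. More peaks in the far part of the autosomes passed 0.05 only when the tied chromosome 19 was left out (p = 0.0309, exact binomial test, also added after seeing the data). Spacing stayed closer than random in each setting that was run, with ratios from 0.318 without chromosome 11 to 0.840 with merging and bins together. The random places had no minimum distance, which raises the ratios of the merged settings. They did not leave out assembly gaps either, which can lower the ratios of all settings. Overlap, start-site window, background, flank and gene-body alternatives were not run, because the comparisons they belong to need mm9 sequence or annotation. No paired analysis was possible because each group has 1 library and only Bio-Tdg has values here. The fewest recovered reads in a peak were 21 and the lowest score 258, the calling threshold and the depth of the library are not known, and a missing peak does not show missing binding.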

Other observations

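The test in this part was chosen after peak and gene numbers per chromosome had been seen. The mitochondrial genome had 1 peak, from 7 to 6565, with a score of 3100. Reads were recovered only below a score ceiling, which limits the recovered density of wide peaks and leaves out 2086 peaks, so the following values do not rank all peaks. Chromosome 10, 41773829 to 41774419, had 154 reads in 591 bp (261 reads per kb), and chromosome 2, 98503673 to 98504384, had 159 reads in 712 bp (223 reads per kb), against a median of 49.5 reads per kb. Without the mock or repeat annotation, repeated sequence and binding cannot be told apart at these 2 peaks either. The most recovered reads, 239 in 4365 bp, were at chromosome 10, 80825730 to 80830094, with a score of 3045 just under that ceiling. Of the 10 most crowded megabases, 9 had median reads per peak above the autosomal median of 42, with a range of 38.5 to 55.5. Across 1807 autosomal bins with at least 5 peaks, which are not independent replicates, Spearman's rho between the number of peaks and their median reads was 0.0831.

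A hypothesis is that the peak density of a chromosome follows its gene density. Across the 19 autosomes, Spearman's rho between peaks per Mb and protein-coding genes per Mb was 0.861 and Pearson's r 0.843 (permutation tests with 100000 resamples, p = 2e-05, the smallest they can give, and p = 4e-05, Benjamini-Hochberg adjusted 4e-05 and 8e-05 over 2 relations). Gene numbers came from RefSeq on GRCm38.p6 and lengths from the mm9 peaks, so the densities are approximate. Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.885 (permutation p = 2e-05). Chromosome 7 had the fewest peaks per gene among the autosomes, at 2.46, and chromosome 15 the most, at 4.18. The other relation, of median reads per peak with gene density, had a rho of 0.731 (permutation p = 0.00042, adjusted 0.00042) and an r of 0.777 (permutation p = 0.00022, adjusted 0.00022), and r was 0.678 without the same chromosomes (permutation p = 0.00512), although the medians ran only from 40 to 44 reads. These values are consistent with peaks lying in or near genes, but also with open, GC-rich or well-mapped sequence, which goes with genes and was not measured here, and chromosomes of a single library are not replicates.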
